A study of Homo sapiens with 6 samples.

How the data were processed

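The series holds 6 tumours grown under the skin of nude mice from Huh7, an established human hepatocellular carcinoma cell line. The cells carried either a plasmid for isoform A of the human insulin receptor (IR-A), with a green fluorescent marker, or the empty vector, and had been selected with G418 and by sorting for fluorescence. Each group has 3 tumours with 1 array each. Per the labels' protocols, total RNA was extracted with Trizol, and 500 ng was converted to biotin-labelled sense-strand DNA with a whole-transcript kit for Affymetrix arrays. The deposited values are log2 signals, 1 per probe set and array. RMA, which corrects background, normalizes between arrays and summarises probes into probe sets, and the Partek software are named in the submitters' processing notes, without versions or roles. The array model, the probe set definition, the genome build and the authors' own test are not given in the sources used here. The scale was read from the values, which had the range that RMA gives on log2. RMA compresses differences of dim probe sets, and a gene-level probe set does not separate isoforms of INSR.

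The table holds 24726 probe sets. GEO's probe annotation pairs 23934 of them with 1 gene symbol and none with several, and 792 were unnamed here and entered only the counts of probe sets. Gene IDs of 23893 named probe sets matched the RefSeq gene table of assembly GRCh38.p14, which was used only for current symbols, of which 0 had to be updated, and for which genes neighbour each other. Of 3 symbols with more than 1 probe set, the probe set with the highest mean over all 6 arrays was kept, which left 23931 genes. No pair of arrays shared more than 4.15% of its values, so no array was a copy of another. 7 probe sets had 1 value on all arrays.

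IR-A tumours were compared with control tumours with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, no filter on dim probe sets), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The design, the gene lists and the other settings were fixed before the data were examined. Each difference is the IR-A mean minus the control mean on the log2 scale, and SE and 95% intervals are the moderated ones. Of 34 gene lists, 26 describe pathways and 8 are markers of cell types that a mouse host could bring. The arrays measured 742 of their 799 memberships. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 34 lists. Camera with an estimated correlation and fry were run beside it. Chromosomes and windows of 50 neighbouring genes were tested with camera too.

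INSR was always named. The rule for other genes took up to 12 per direction with an adjusted p under 0.05 and groups that did not overlap. As fewer passed, it took the 6 genes of smallest unadjusted p per direction, which are stated as not passing. Of each list it took up to 4 members past the threshold or, where none passed, the 2 of smallest unadjusted p. The rule gave 75 genes, and genes named outside it are stated as such. Histone genes have near-identical copies, so their probe sets are uncertain as to the copy. Other gene families were not checked for signal shared between members.

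The scripts were tested on 20 simulated data sets of 24726 probe sets for the comparison of 3 against 3 tumours. Means came from the real arrays, and spreads were drawn at random from the distribution that limma fitted to them. The limma fit recovered 61.4% of genes changed by 1 on the log2 scale, 92.8% of those changed by 2 and 97.3% of those changed by 3. It called 0.0398% of unchanged probe sets. Camera, run on 23931 genes, called a list shifted by -0.5 in 20 of 20 simulations and 0.303% of unshifted lists. Simulated genes were independent, unlike real ones, and no simulated tumour stood apart from its group. These rates therefore check the scripts and do not carry over to the real tumours. There, INSR with a log2 difference of 2.95 did not pass, and a split that mixed the groups called 13 lists.

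The alternatives were quantile normalization of the deposited values, centring of each array on its median, leaving out the dimmest 25% or 50% of probe sets, an intensity trend, robust or no moderation, array weights, the replicate number as a block, and leaving out each tumour. Other thresholds, the mean of a gene's probe sets, and lists without shared members were also tried. Lists without INSR were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.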

Results

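Gene expression was measured on Affymetrix arrays in 6 tumours that Huh7 cells, a human hepatocellular carcinoma line, formed under the skin of nude mice. In 3 tumours the cells overexpressed isoform A of the insulin receptor (IR-A), and in the other 3 they carried the empty vector (control). The comparison asks how transcript levels of the tumours differed with the added receptor. The values were log2 signals of 24726 probe sets, 23934 of which had a gene symbol. The number of arrays limits the precision. Nothing in the labels says which mouse or culture each tumour came from, so p-values measure only the spread between these samples, which may be technical. An exact permutation test of 3 against 3 values cannot go below p = 0.1.

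The transcript of the insulin receptor gene, INSR, was 7.75-fold more abundant in IR-A tumours. IR-A tumours also had more signal for complement and acute phase genes such as C3 and LBP and for genes of hepatocyte function, and less for genes of the cell cycle. As fixed lists, these groups were shifted against the other genes, but with an estimated correlation between genes no list was called (lowest adjusted p = 0.263). No single gene passed limma's test after adjustment.

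INSR lay at 8.04 ± 0.43 (SD, n = 3) in control and 10.99 ± 0.33 (SD, n = 3) in IR-A tumours, a log2 difference of 2.95 with SE 0.26 and a 95% interval from 2.34 to 3.57. The adjusted p from limma was 0.0769. The control arrays read 8.04, 7.61 and 8.47 and the IR-A arrays 10.65, 11.31 and 11.01, so the groups did not overlap. The difference passed the threshold without control tumour 2 (adjusted p = 0.0261), without the dimmest 25% (0.0471) or 50% (0.0350) of probe sets, and with array weights (0.0480). Over all alternatives, its adjusted p ran from 0.0261 to 0.464. The probe set does not separate isoform A from isoform B.

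**Figure D1:**
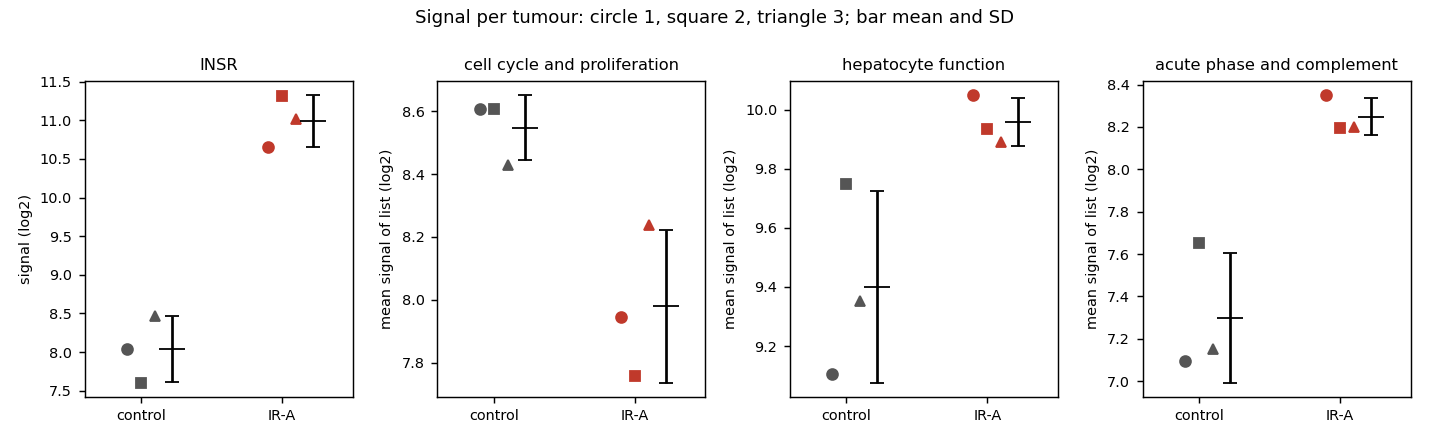
Signal per tumour on the log2 scale for INSR and the mean over the members of 3 gene lists, with circles, squares and triangles for tumours 1, 2 and 3 of each group and bars for the mean and SD. INSR of control tumour 2 (7.61) was the lowest of all tumours, while its hepatocyte mean (9.75) lay closer to the IR-A tumours (9.89 to 10.05) than to the other controls (9.10 and 9.35).

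Of 24726 probe sets, 0 passed an adjusted p of 0.05 in limma, and 18 passed 0.1, 8 higher and 10 lower in IR-A tumours. At an unadjusted p under 0.05 there were 3493 probe sets (14.1%), 1755 higher and 1738 lower, and with 1 tumour left out that number ran from 2156 (without IR-A tumour 1) and 2226 (without control tumour 1) to 5206 (without control tumour 2). The groups did not overlap in 4248 probe sets (17.2%). Random labels would give 10% on average. Probe sets move together and no spread around 10% was computed, so the excess was not tested. Control tumour 2 stood apart from its group. Its mean correlation with the other controls across probe sets was 0.982, against 0.987 with the IR-A tumours. Without it, 308 probe sets passed, 197 higher and 111 lower. Array weights gave 11 probe sets, and leaving out the dimmest 25% or 50% gave 14 and 20.

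The genes of smallest p, all at an adjusted p of 0.0769, included 6 with higher signal. Besides INSR they were LBP, the lipopolysaccharide-binding protein, with a log2 difference of 2.23 (SE 0.23), and complement component C3, with 1.78 (SE 0.19). MR1, which presents microbial vitamin metabolites to T cells, differed by 1.17 (SE 0.11), USH1C, a scaffold protein of microvilli, by 1.08 (SE 0.11), and GYS1, a glycogen synthase, by 0.84 (SE 0.08). On the lower side were MND1, a factor of meiotic recombination, at -1.45 (SE 0.12), the small nucleolar RNA host gene SNHG19 at -1.27 (SE 0.10), and the small nucleolar RNA SNORD50B at -1.44 (SE 0.15). The histone genes H2AC13 (-1.39), H4C2 (-1.29) and H2BC13 (-1.25) completed the 6 that the rule took on the lower side. Near-identical copies make the source of their signal uncertain. Without control tumour 2, these 12 genes had adjusted p values from 0.0255 to 0.0328 in limma. The genes were chosen for small p in the same tumours, so these values are no added support.

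**Figure D2:**
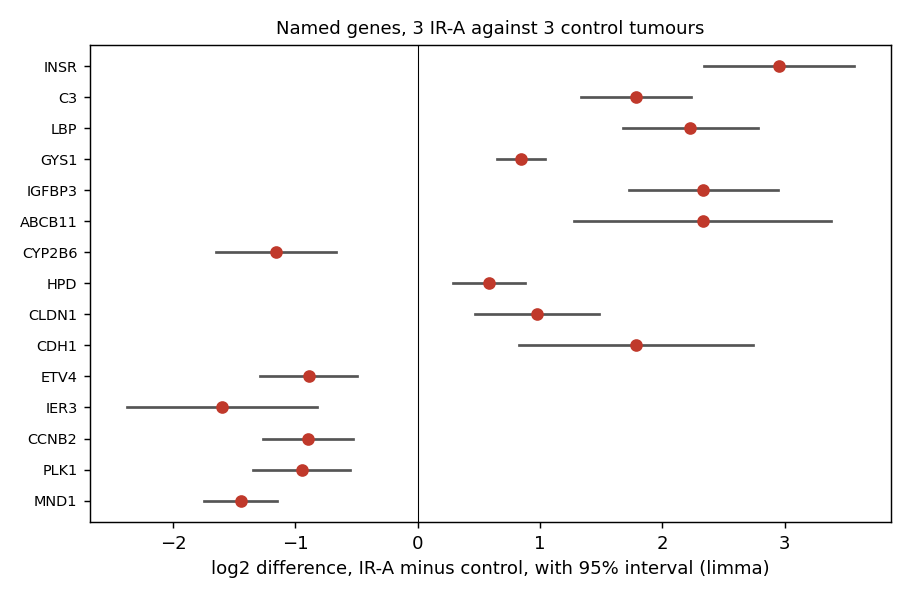
Log2 differences of 15 named genes, IR-A minus control, as points with 95% intervals from limma (n = 3 per group). None passed the adjusted threshold, and the points run from -1.60 for IER3 to 2.95 for INSR.

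The acute phase and complement list was shifted higher in IR-A tumours (median log2 difference 0.78, 21 of 24 genes above 0, camera adjusted p = 7.27e-13). The adjusted p was 0.263 with an estimated correlation. No member passed over all genes, and 13 were higher when adjusted over the list alone. List members without an SE here and in the following lists were chosen after their values were seen. Among these were the plasma carriers haptoglobin, HP (2.21), and hemopexin, HPX (2.23), the complement protease C1S (2.44), the complement regulator CFI (1.95) and the protease inhibitor SERPINA3 (1.69). The list mean was 7.65 in control tumour 2, 7.10 and 7.15 in the other controls, and 8.20 to 8.35 in IR-A tumours.

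The hepatocyte function list was also shifted higher (median 0.39, 29 of 33 above 0, adjusted p = 3.17e-09, and adjusted p = 0.263 with an estimated correlation). None of its members passed over all genes and 4 were higher adjusted over the list alone. They were the bile salt export pump ABCB11 (2.33, SE 0.44), HP, the bile acid enzyme CYP8B1 (1.73) and the tyrosine-degrading enzyme HPD (0.58, SE 0.12). The cytochrome P450 and drug metabolism list had a median of 0.19 with 19 of 25 genes above 0 (adjusted p = 0.0275, and adjusted p = 0.450 with an estimated correlation). Its mean in control tumour 2 (5.93) lay within the range of the IR-A tumours (5.78 to 6.06). The mean difference was 0.42, against 0.65 without control tumour 2 (adjusted p = 0.00105) and 0.27 without control tumour 1, where the call was lost (adjusted p = 0.112). The call was also lost without control tumour 3 or IR-A tumour 1. ADH1A, an alcohol dehydrogenase, differed by 2.47 (SE 0.64), while the drug-metabolising CYP2B6 differed by -1.16 (SE 0.21) and was the 1 member lower adjusted over the list alone.

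The FOXO1 targets that insulin represses were shifted higher as a list (median 0.29, 14 of 19 above 0, adjusted p = 0.000183, and adjusted p = 0.263 with an estimated correlation). INSR itself is a member, and without it the adjusted p was 0.00152. Adjusted over the list alone, 4 members were higher and 1 lower. Beside INSR, the higher ones were the metabolic coactivator PPARGC1A (1.44), the stress protein SESN3 (0.82) and the cyclin CCNG2 (1.05, SE 0.19), and the lower one was the receptor substrate IRS2 (-0.51). The insulin and IGF pathway list was not called (median 0.14, 21 of 33 above 0, adjusted p = 0.0766), with 3 members, INSR among them, higher and 2 lower adjusted over the list alone. Without INSR its mean of 0.18 was 0.091 (adjusted p = 0.204). Its member IGFBP3, which binds insulin-like growth factors, differed by 2.34 (SE 0.25, adjusted p = 0.0809), and PIK3R1, a regulatory subunit of phosphoinositide 3-kinase, by 1.25.

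Fatty acid oxidation and PPARA targets were shifted higher (median 0.22, 19 of 24 above 0, adjusted p = 0.000407, and adjusted p = 0.279 with an estimated correlation), with 0 members passing adjusted over the list alone. CPT1A, which controls fatty acid entry into mitochondria, differed by 2.68 (SE 0.59) and the nuclear receptor PPARA by 1.19 (SE 0.30). De novo lipogenesis genes had a median of 0.08 with 14 of 19 above 0 (adjusted p = 0.0275, and adjusted p = 0.263 with an estimated correlation). The list mean of 0.27 was 0.18 without control tumour 1. The call was lost without IR-A tumour 2 or 3 and without the dimmest 50% of probe sets. PNPLA3 (0.67, SE 0.16) and DGAT2 (0.70, SE 0.22), both of triglyceride metabolism, had its smallest p values. In both lists control tumour 2 had the highest mean of the controls (7.84 and 7.99).

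The cell cycle and proliferation list was shifted lower in IR-A tumours (median -0.59, 30 of 32 genes below 0, adjusted p = 3.56e-15, and adjusted p = 0.263 with an estimated correlation). None of its members passed over all genes, and 24 were lower adjusted over the list alone. Examples were the mitotic kinase PLK1 (-0.95, SE 0.17), the mitotic cyclins CCNB2 (-0.90, SE 0.15) and CCNB1 (-0.88), and the replication helicase subunit MCM2 (-0.83). Control tumour 2 lay with its group here, at a list mean of 8.61 against 8.61 and 8.43 in the other controls and 7.76 to 8.24 in IR-A tumours. MAPK output and feedback genes were shifted lower as well (median -0.36, 21 of 23 below 0, adjusted p = 6.51e-05, and adjusted p = 0.263 with an estimated correlation). The transcription factor ETV4 (-0.89, SE 0.17), the early response gene IER3 (-1.60, SE 0.32) and the MAPK inhibitor SPRED2 (-0.66) were lower adjusted over the list alone. The p53 targets were shifted higher (median 0.20, 16 of 20 above 0, adjusted p = 0.000544, and adjusted p = 0.263 with an estimated correlation). TP53INP1, a stress-induced p53 partner, differed by 2.45 (SE 0.48) and was the 1 member higher adjusted over the list alone, and ZMAT3 differed by 0.93 (SE 0.28).

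Epithelial junction and polarity genes were shifted higher (median 0.33, 17 of 23 above 0, adjusted p = 0.000481, and adjusted p = 0.263 with an estimated correlation). E-cadherin, CDH1 (1.79, SE 0.40), and the tight junction protein CLDN1 (0.98, SE 0.21) were the 2 members higher adjusted over the list alone. Interferon-stimulated genes were shifted higher too (median 0.26, 19 of 28 above 0, adjusted p = 6.51e-05, and adjusted p = 0.263 with an estimated correlation). The antiviral membrane proteins IFITM2 (2.14, SE 0.24), BST2 (1.27, SE 0.25) and IFITM3 were higher adjusted over the list alone. BST2 was dim in control tumours, at 3.49, against 4.76 in IR-A tumours. IFITM2 and IFITM3 are of 1 gene family, and whether their probe sets separate them was not checked.

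Genes of antigen presentation by HLA class I had a median of 0.14 with 11 of 12 above 0 (adjusted p = 0.00708, and adjusted p = 0.263 with an estimated correlation). The peptide-loading protein TAPBP (0.85, SE 0.20) and the immunoproteasome subunit PSMB9 (0.46, SE 0.12) were higher adjusted over the list alone. PSMB9 was dim, at 3.63 in control and 4.09 in IR-A tumours. The call was lost without IR-A tumour 3 and without the dimmest 50% of probe sets. The NF-kB and cytokine list was called higher (adjusted p = 0.0476, and adjusted p = 0.326 with an estimated correlation), yet its median was -0.0043 and its mean 0.21, so that median and test differed in sign. SOD2, a mitochondrial superoxide dismutase (0.76, SE 0.14), was the 1 member higher adjusted over the list alone, and the chemokine CXCL10 differed by 2.36 (SE 0.60). The call was lost without control tumour 2, control tumour 3 or IR-A tumour 3, and in 6 more settings with the preset correlation.

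**Figure D3:**
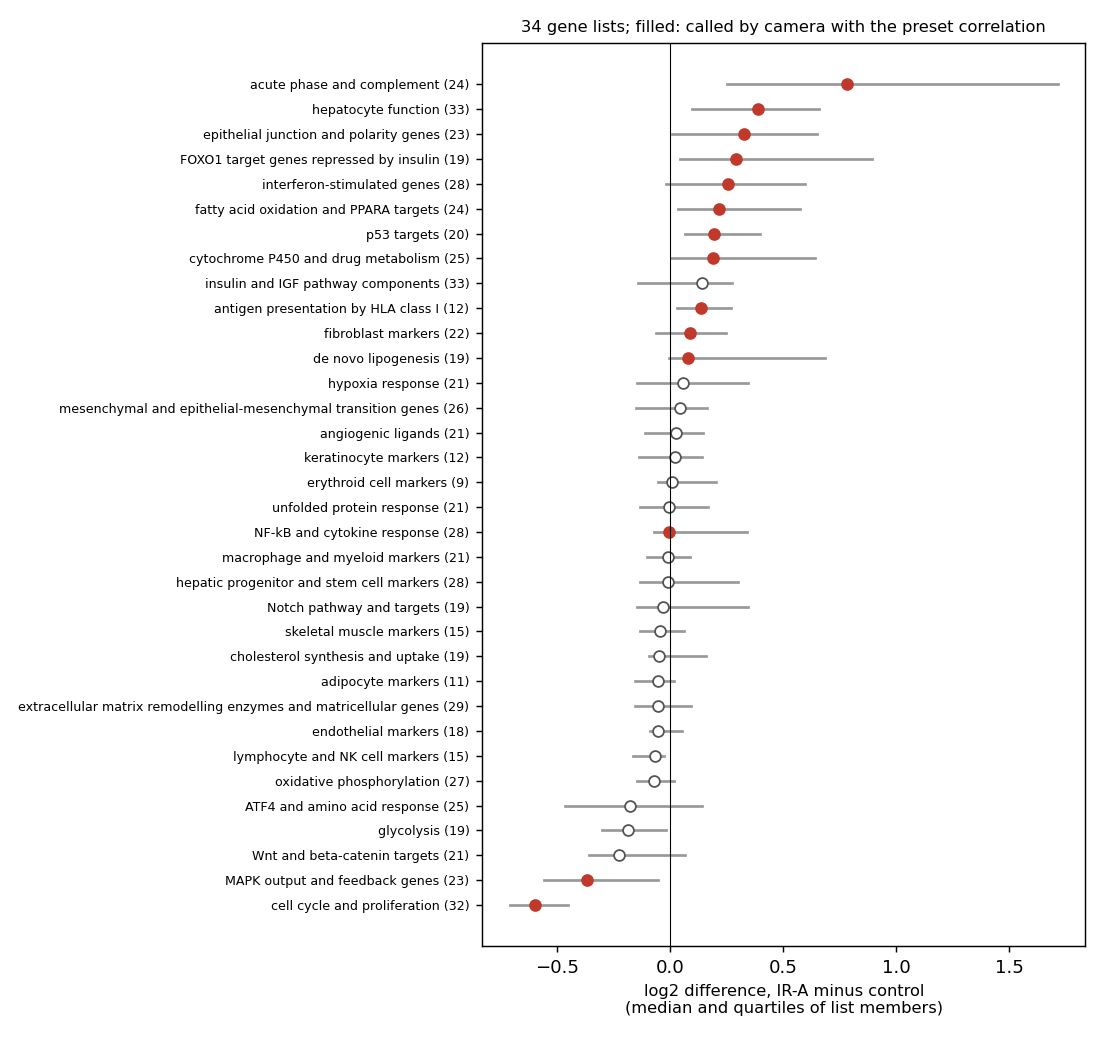
Median log2 difference (points) and quartiles (lines) of the measured members of 34 gene lists, IR-A minus control, with member numbers in parentheses. Filled points are the 14 lists called by camera with the preset correlation, 12 higher and 2 lower, from -0.59 for the cell cycle to 0.78 for acute phase and complement.

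Among markers of cells that a mouse host could bring, 1 of 8 lists was called. The probe sets are of human genes, so mouse RNA would be read only where it binds to them. Medians near 0 therefore do not measure host content. Control means of the erythroid (3.87), keratinocyte (3.89), endothelial (4.08) and skeletal muscle (4.09) lists were dim, below the median probe set (4.71). Fibroblast markers had a median of 0.09 with 14 of 22 above 0 (adjusted p = 0.0346, and adjusted p = 0.263 with an estimated correlation). The call was lost without control tumour 2 or IR-A tumour 3, and in 4 more settings with the preset correlation. The collagen-binding proteoglycan LUM differed by 1.26 (SE 0.15) and was the 1 member higher adjusted over the list alone. LUM was dim, at 2.98 in control and 4.24 in IR-A tumours. COL1A2 differed by 0.83 (SE 0.20). Endothelial (-0.05), lymphocyte and NK cell (-0.07), erythroid (0.01), skeletal muscle (-0.04) and keratinocyte (0.02) markers had medians near 0. Their camera adjusted p values ran from 0.332 to 0.822. Macrophage markers (median -0.0095, adjusted p = 0.748) differed in sign between median and test, and their signalling adaptor TYROBP (1.78, SE 0.29) was the 1 member higher adjusted over the list alone. Adipocyte markers had a median of -0.05 and a mean of 0.15 (adjusted p = 0.822), or 0.096 without control tumour 1, with 2 members higher, among them the lipid droplet protein PLIN1 (1.64, SE 0.46), and 1 lower adjusted over the list alone.

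The remaining pathway lists were not called. Their medians were -0.22 for Wnt and beta-catenin targets, -0.19 for glycolysis, -0.17 for the ATF4 and amino acid response, -0.07 for oxidative phosphorylation, -0.05 for matrix remodelling and -0.03 for the Notch pathway. Hypoxia genes had a median of 0.06, mesenchymal genes 0.05, angiogenic ligands 0.03, cholesterol synthesis -0.05, hepatic progenitor markers -0.0096 and the unfolded protein response -0.0028. The camera adjusted p values of these 12 lists ran from 0.160 to 0.982. Cholesterol, Notch, progenitor and unfolded protein lists differed in sign between median and test. Glycolysis was called lower without control tumour 2 (adjusted p = 0.00105), hypoxia higher without control tumour 3 (0.000163) or IR-A tumour 1 (0.0355), and Wnt targets lower without control tumour 3 (0.0166). The mean of the Wnt list was -0.36, against -0.53 without control tumour 3 and -0.18 without control tumour 1 (adjusted p = 0.466). Adjusted over their own lists alone, the integrin subunits ITGA5 (1.47, SE 0.24) and ITGB3 (1.34, SE 0.27), the Notch ligand JAG1 (0.54, SE 0.09), the protease inhibitor TIMP2 (1.16, SE 0.20) and the degradation factor SEL1L (0.55, SE 0.11) were higher, and the growth factor TGFB1 (-1.08) was lower. The stem cell marker LGR5 (-1.94, SE 0.70), MYC (-1.24, SE 0.43), the drug efflux pump ABCG2 (-1.29, SE 0.34) and the amino acid transporter SLC7A5 (-1.11, SE 0.24) had lower signal without passing.

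No chromosome was shifted, with 0 of 24 called by camera, 0 at an unadjusted p under 0.05 and a lowest adjusted p of 0.933. Of 466 windows of 50 neighbouring genes in the order of GRCh38.p14, 15 were called with the preset correlation, the only one used for windows. No gene list kept its call with an estimated correlation, so whether these windows would is not known. The smallest p belonged to the window from H1-1 to POM121L2 on chromosome 6 (median -0.36, adjusted p = 9.21e-09), which holds 32 histone genes. The next was the window from PCDHB10 to LINC01844 on chromosome 5, with a median of 0.21 (adjusted p = 0.000777).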

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

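The lists without INSR were chosen after the data were seen. Signal over background was not measured per probe set, so dim genes carry the least certain differences. The count of probe sets called, 0 as reported, was 14 without the dimmest 25% and 20 without the dimmest 50% of probe sets. There fewer were tested, and limma's moderation was fitted anew, which also changed the p-values. With array weights the count was 11. The counts of named genes were 14, 20 and 11 as well. Leaving out 1 tumour gave 0 to 308 probe sets and 0 to 300 named genes, with calls only without control tumour 2. At looser thresholds, 18 probe sets had an adjusted p under 0.1 and 1470 an unadjusted p under 0.05 with a 1.5-fold difference. INSR kept its direction in all 15 settings run on it (log2 difference 2.74 to 3.17 over left-out tumours). It was called without the dimmest 25% (2.95) or 50% (2.95), with array weights (2.87), and without control tumour 2 (2.74). The 95 other genes named by the rule or added to it kept their direction in every setting run on them. They were chosen by their values in these same tumours, and filters and moderation leave a difference unchanged. Their kept direction is therefore little support. Their side of the threshold did change: 12 passed without the dimmest 25%, 12 without the dimmest 50%, 9 with array weights and 36 without control tumour 2. Of the 14 lists, 0 were called with an estimated correlation and 0 by fry; other settings called 10 to 14. Chromosomes had 0 calls in each setting. Robust moderation and no moderation do not alter camera, so lists and chromosomes have no value there. The cause of these changes was not tested.

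The labels do not say whether numbers 1 to 3 pair the tumours. Deviations of same-numbered tumours from their group means correlated at -0.29, -0.36 and 0.02 across probe sets. The highest value of any pair was 0.50, for control tumour 2 with IR-A tumour 1. These values show no pairing by number. Deviations within a group of 3 depend on each other, so they cannot exclude shared mice or batches. With the number as a replicate block, 0 probe sets and 12 lists were called, and the INSR difference was 2.95.

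List means changed sign only in lists that were not called, in settings that did not call them. Means of matrix remodelling genes were 0.0089 with centred arrays, 0.017 without the dimmest 50% and 0.090 without shared members. Angiogenic ligands had -0.0038 without the dimmest 25%, -0.014 with array weights and -0.035 without shared members. Array weights gave -0.014 for hypoxia, -0.00052 for erythroid and -0.025 for keratinocyte markers. Progenitor markers had 0.047 without shared members. Over left-out tumours, means ran from -0.37 to 0.045 for glycolysis, -0.19 to 0.37 for hypoxia, -0.12 to 0.032 for progenitor markers, -0.016 to 0.088 for mesenchymal genes and -0.046 to 0.053 for angiogenic ligands. The ranges were -0.0079 to 0.14 for the unfolded protein response, -0.10 to 0.0038 for oxidative phosphorylation and -0.10 to 0.085 for matrix remodelling. They were -0.072 to 0.0065 for endothelial, -0.042 to 0.075 for erythroid and -0.065 to 0.076 for keratinocyte markers. The cause was not tested.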

Other observations

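The gene families below, and the tests of a mislabelled sample, of the share of tumour cells, of short RNA as a cause of the lower cell cycle messages and of S phase, were chosen after the values were seen. Replication-dependent histone genes, which supply chromatin during DNA synthesis, had lower signal in IR-A tumours (median log2 difference -0.96, 51 of 54 below 0, camera adjusted p = 1.33e-28 over the 7 families). Cytosolic ribosomal protein genes had a median of -0.41 with 52 of 55 below 0 (adjusted p = 4.29e-18). With an estimated correlation, the adjusted p was 0.0678 for each of these families. Small nucleolar RNA genes, which guide the modification of ribosomal RNA, had medians of -0.54 (C/D box, 186 of 222 below 0, adjusted p = 1.06e-18) and -0.47 (H/ACA box, 76 of 89 below 0, adjusted p = 7.30e-11). With an estimated correlation these were adjusted p = 0.107 and 0.195. Metallothionein genes, which bind zinc and copper, had a median of -0.93 with 8 of 9 below 0 (adjusted p = 4.58e-05, and 0.135 with an estimated correlation). Whether probe sets separate the metallothionein genes was not checked. Histone means were at least 6.95 in control and at most 6.28 in IR-A tumours, while H/ACA means overlapped, as IR-A tumour 2 (7.16) lay above control tumour 2.

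The following genes outside the lists were chosen after their values were seen, and whether they share a function was not tested. The complement component C6 differed by 3.78 (SE 0.61), the liver-secreted protein FETUB by 3.44 (SE 0.91), the glucuronosyltransferase UGT2A3 by 2.78 (SE 0.54) and the bile acid enzyme AKR1D1 by 2.76 (SE 0.76). The growth factor FGF19, which represses bile acid synthesis, differed by -1.96 (SE 0.28), and the metallothionein MT1G by -1.92 (SE 0.49). None passed the adjusted threshold (limma adjusted p = 0.126 to 0.212). Without control tumour 2, C6 differed by 4.47 (adjusted p = 0.0261), FETUB by 4.56 (0.0255), UGT2A3 by 3.33 (0.0395) and FGF19 by -2.24 (0.0261), which passed, while AKR1D1 (3.51, adjusted p = 0.0618) and MT1G (-2.32, adjusted p = 0.0798) did not. In each of these genes control tumour 2 was the control nearest the IR-A tumours, so leaving it out had to widen the difference. These passes are therefore no added support, and no probe set passed with any other tumour left out.

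Control tumour 2 lay closer to the IR-A arrays than to the other controls. A mislabelled IR-A tumour is argued against by INSR, which in control tumour 2 lay at -3.046 on the log2 scale relative to the lowest IR-A tumour. Its spread of signal was wider than in the other controls and close to that of IR-A tumour 1 (SD 2.20 on both arrays). Its mean correlation with IR-A arrays exceeded that with the other controls by 0.00488. After quantile normalization the excess was 0.00432, so on these arrays the spread does not account for all of it. The bootstrap SE of 0.00028 was over probe sets and does not measure variation between tumours. A tumour that differs in hepatocyte gene expression stays open, and no biological explanation was tested, as the labels describe no difference among controls.

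Cell cycle genes were lower while hepatocyte and acute phase genes were higher in IR-A tumours. A lower share of tumour cells would lower both groups of genes, unless normalization between arrays hid this. It would raise markers of host cells only where mouse RNA binds probe sets of human genes. The hepatocyte list mean lay above 0 by 0.556 (SE 0.19 over arrays), which a lower share alone would not give. That direction was known beforehand, so it was no separate test. Of the 8 host marker lists, 1 was called, fibroblast markers, with higher signal. The lists not called cannot exclude more host cells, as these probe sets may miss mouse RNA. A lower share beside another difference stays open. Scaling of arrays that depends on signal would shift random lists matched on mean signal as well. Such lists, 10000 for each, averaged 0.016, -0.068 and -0.013 for the cell cycle, hepatocyte and acute phase lists. The real list means were -0.57, 0.56 and 0.95, which argues against such scaling as their source. The real means lay at percentiles 0, 100 and 100. These percentiles do not measure how unusual the lists are, as random genes were drawn independently and list members are correlated. A difference brought by the receptor, and a difference between separately selected cell populations, both stay open and may act together, as each group came from 1 kind of transfected cells.

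Histone and small nucleolar RNA genes were lower together, and lower recovery of short RNA stays open, as the short ribosomal protein and metallothionein messages had lower medians too. The long host genes of small nucleolar RNAs had a median of -0.2905 (upper quartile -0.05, adjusted p = 0.101 with an estimated correlation), which by the limit set before the test, though SNHG19 had been seen by then, spoke against it. That limit was set aside afterwards because it took host genes and their RNAs to move together, whereas control tumour 2 had the highest host mean (6.52) and the lowest C/D mean (6.03) of the controls, and IR-A tumour 2 the reverse (5.86 and 5.87). The cell cycle mean of -0.5678 (SE 0.15 over arrays) was known beforehand and does not bear on short RNA. For the histone genes, fewer cells in S phase stays open: the mean of 12 S phase genes was -0.4967 (SE 0.15 over arrays, adjusted p = 0.135 with an estimated correlation), but all 12 belong to the cell cycle list whose direction was already known, so this decides nothing.

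The 6 tumours make 10 splits into 3 against 3, too few for a share under 0.05. The real split called 0 probe sets and 0 named genes, and the highest of the others also called 0 of each, so all 10 splits gave as many. At an unadjusted p under 0.05, 1 of 10 splits gave as many probe sets as the real one, which had 3493 against 3114 for the highest other. For gene lists called by camera it was 1 of 10 as well, with 14 in the real split and 13 in the highest other, which put control tumour 2 with IR-A tumours 1 and 2. For chromosomes all 10 splits gave at least the 0 of the real split, and the highest other had 1.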
